A study of Mus musculus with 14 samples.

How the data were processed

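Total RNA of cultures of mouse bone marrow stromal cells, the adherent cells of the marrow, was measured on Affymetrix MG-430 2.0 expression arrays. Per the labels' protocols, stroma was grown from femora of mice carrying a floxed Nemo gene (Ikbkg, the regulatory subunit of the IkB kinase complex), the knockout was made in culture with 1 µM Tat-Cre, a cell-permeable recombinase, and knockout stroma was kept for at least 8 days before use. Stroma was then cultured for 5 days with primary human chronic lymphocytic leukaemia (CLL) cells, in large excess. The leukaemic cells were washed off and depleted on anti-CD19 beads, and 200 ng of stromal RNA was labelled. There were 14 arrays, 7 of Nemo wild type and 7 of Nemo knockout stroma, and 7 CLL samples that were each used once in either group. The arrays that share a CLL sample are called a pair and are numbered 1 to 7. Whether wild type cultures were exposed to a control protein, or kept as long in culture, was not given in the sources used here.

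The deposited values were one intensity per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes; its version and settings were not given in the sources used here. MAS5 combines the probe pairs of a probe set after subtracting mismatch signal and scales each array to a common mean. From the values, the mean after removal of 2% of probe sets at either end was 1000 on every array, so levels are relative to the array's own mean, and a shift shared by most genes would not be seen. No detection calls were used here, and dim probe sets are noisy after mismatch subtraction. The number of arrays limits the precision.

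The value table held 45101 probe sets, of which 34958 had 1 gene symbol in the platform annotation, 932 had several and 9211 had none in the table used here. Only probe sets with 1 symbol were named. Of these, 34754 matched a gene identifier in the reference table and 0 symbols needed an update. No genome was used, so no coordinates are given. Intensities were converted to log2(signal + 16); this pseudocount understates the change of dim genes. The dimmest 40% of all probe sets by mean over the 14 arrays, those with a mean log2 under 7.27, were left out, which left 27060. For each gene the probe set with the highest mean was kept, which gave 12408 genes.

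Knockout and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), 2-sided, with Benjamini-Hochberg adjustment over the 12408 genes and a threshold of 0.05. Differences are knockout minus wild type on the log2 scale with the standard error (SE) of the fit, and ± marks the standard deviation (SD) over arrays. The labels do not say whether the cultures of one group came from separate mice, so stroma may be shared between cultures to an unknown extent. Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over 33 lists, with an estimated correlation and with fry as alternatives. The last of these lists held mouse sex-linked transcripts, served to keep them out of the named genes, and had a camera adjusted p = 0.252. By fry it passed over all pairs (adjusted p = 0.0244). In pairs 1 to 5 alone it had a median of -1.80 and a camera adjusted p = 0.0464 (adjusted p = 0.186 with an estimated correlation). There 3 of its 4 tested members passed as lower in the knockout and none as higher. Fry tests whether the genes of a list move, on balance, one way, and does not compare the list with other genes. Medians, counts of called members and counts adjusted over the list alone accompany each test.

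The groups, lists, tests, thresholds and alternatives were fixed before the data were examined, as was the rule for named genes. That rule takes Ikbkg, Il1a, Il15, Prkcb, Cxcl12, Vcam1, Icam1, Ccl2, Il6 and Tnfsf13b whatever their values. It adds the 12 genes with the largest fold in each direction among called genes with the same sign in at least 6 of the 7 pairs. From each list described with examples it takes up to 4 called members with the smallest p, or up to 2 as values where none was called.

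The pairing comes from the labels, since each CLL sample was used in both groups. Deviations from the group means correlated within pairs at r from -0.03 to 0.21 (median 0.14, over 0.1 in 5 of 7 pairs), against a median of -0.002 between arrays of different pairs. Within the sets of pairs described next, the median was 0.05. The CLL sample as a block is an alternative and is quoted beside a result only where it changes a call.

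Pairs 6 and 7 stood apart from pairs 1 to 5 in both groups, which was seen only after the data were examined. The labels give no batch. The split was seen in the principal components of the same values that are tested here. Tests between the sets therefore do not use an outside grouping. The 3′ to 5′ ratios of control probe sets, which rise when labelled RNA is short, parted the same arrays in both groups. Values within each set come from one limma model with 4 groups of arrays (5, 5, 2 and 2) that share an estimate of the spread. The difference between the sets was tested as an interaction. For some genes, such as Icam1, Il1a and Crabp1, knockout replicates 6 and 7 lay far apart. The shared estimate may be too small for such genes, and so may their p-values within pairs 6 and 7. The mean of a list per array was compared in the same 4 groups by a linear model on 10 residual degrees of freedom, for NF-κB targets, cell cycle genes and macrophage markers; the change between the sets was tested by exact permutation of the 7 pair differences, and both were added last. Pseudocounts of 1 and 64, quantile normalization, median centring, other brightness filters (none, and 60% left out), other probe set rules, no intensity trend, array weights, a threshold of 0.01, each array left out, and the CLL sample as a fixed or random block were also run. The code was tested on simulated data with 12408 genes of which 200 were changed. With the spread within groups, 12% of changes of 0.5, 48% of changes of 1, 86% of changes of 2 and 96% of changes of 3 on the log2 scale were recovered, with 0 false calls. With the spread within groups and sets of pairs there were 12 false calls (6.82% of calls). In the simulated list test a shifted list passed and 0 of 24 lists that shared no gene with it did. Simulated genes were drawn independently, whereas the estimated correlation in the data was 0.36 for NF-κB targets, 0.42 for cell cycle genes and 0.87 for macrophage markers. That test therefore does not show how often camera would falsely call lists of correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.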

Results

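Expression was measured in 14 cultures of mouse bone marrow stromal cells after 5 days with primary human CLL cells: 7 of Nemo wild type stroma and 7 of Nemo knockout stroma, with 7 CLL samples each used once in both groups. Nemo, encoded by Ikbkg, is the subunit of the IkB kinase complex needed for canonical NF-κB activation. The comparison asks what canonical NF-κB signalling contributes to gene expression in stroma exposed to leukaemic cells. All values are log2(MAS5 signal + 16), and differences are knockout minus wild type. The median signal over all probe sets was 276 ± 28.2 (SD, n = 7) in wild type and 215 ± 39.6 (SD, n = 7) in knockout cultures. Every array was scaled to a trimmed mean of 1000. The lower median lay mostly in pairs 1 to 5, with 268 ± 25.1 in wild type and 192 ± 5.8 in knockout arrays (SD, n = 5 each). In pairs 6 and 7 it was 298 in wild type and 273 in knockout arrays (n = 2 each).

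The knockout arrays of pairs 1 to 5 stood apart from all others, and pairs 6 and 7 stood apart in both groups. Component 1 (59.2% of the variance) held the knockout arrays of pairs 1 to 5 at a mean of 83.0 ± 7.04 (SD, n = 5), far from all other arrays. The knockout arrays of pairs 6 and 7 had a mean of -27.6 on it, and the wild type arrays had means of -49.0 in pairs 1 to 5 and -57.4 in pairs 6 and 7. Component 2 (13.3%) parted pairs 6 and 7 from pairs 1 to 5 in both groups. The 3′ to 5′ difference of the GAPDH control probe sets, which rises when labelled RNA is short, was 2.23 in wild type and 2.06 in knockout arrays of pairs 6 and 7 (n = 2 each). It was 0.21 ± 0.29 in wild type and -0.10 ± 0.11 in knockout arrays of pairs 1 to 5 (SD, n = 5 each). The mouse stroma itself differed between these sets: mouse Xist, the transcript of X inactivation, averaged 14.59 ± 0.24 over the 10 cultures of pairs 1 to 5 and 8.32 ± 0.41 over the 4 cultures of pairs 6 and 7. The labels name stroma from both Nemo F/F and Nemo y/F mice without tying either to an array. Values within the sets of pairs, pairs 1 to 5 first, are therefore given beside pooled ones, above all where a call was not met in pairs 6 and 7.

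**Figure D1:**
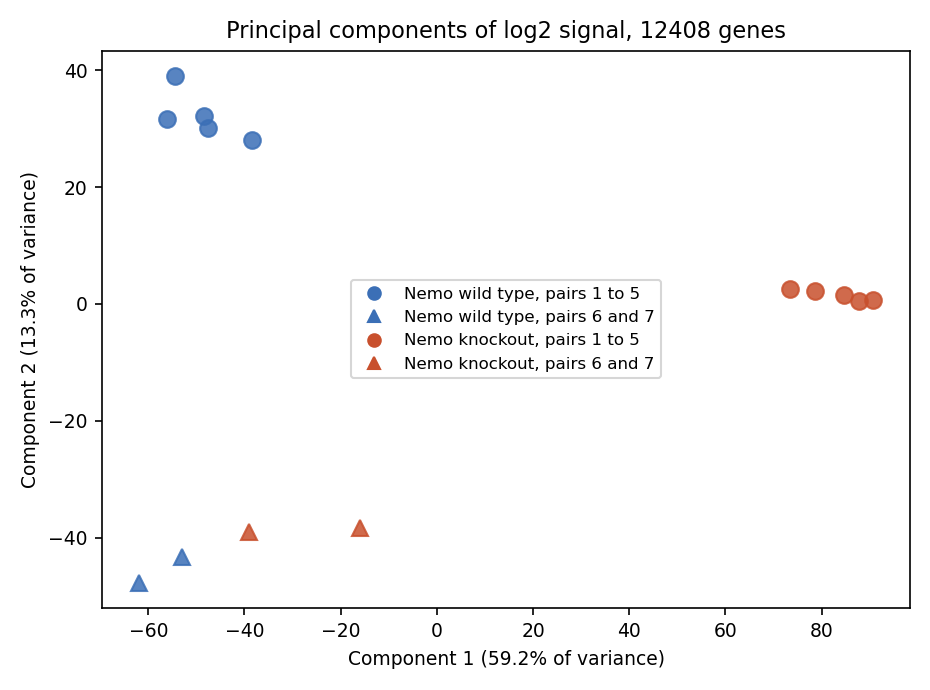
First and second principal components of log2 signal over 12408 genes, with 59.2% and 13.3% of the variance on the axes. Each point is 1 of 14 arrays, coloured by group and shaped by set of pairs; the 5 knockout arrays of pairs 1 to 5 lie at 83.0 on average on component 1, and arrays of pairs 6 and 7 lie lowest on component 2.

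Ikbkg was lower in the knockout arrays in all 7 pairs. Its level was 10.69, 11.12, 10.90, 11.08, 10.96, 11.46 and 10.88 in wild type replicates 1 to 7, and 9.35, 9.49, 9.40, 9.13, 9.32, 10.77 and 10.32 in knockout replicates 1 to 7. The difference was -1.33 (SE 0.24, adjusted p = 0.000713), a 2.52-fold lower signal. It was -1.61 in pairs 1 to 5 (adjusted p = 9.09e-08) and -0.63 in pairs 6 and 7 (adjusted p = 0.0822), and the sets differed (adjusted p = 0.011). The other 5 probe sets of the gene gave differences from -1.76 to -0.79 over all pairs. In pairs 6 and 7 they gave values from -0.57 to 1.04, and no probe set passed there. Where these probes lie relative to the deleted part of the gene was not given in the sources used here.

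Expression differed widely between knockout and wild type cultures: 5043 of 12408 genes (40.6%) changed, 2778 higher and 2265 lower. Of these, 1215 were at least 2-fold higher and 1323 at least 2-fold lower, and 3073 had the same sign in all 7 pairs. Within the sets, 7826 genes passed in pairs 1 to 5 and 1564 in pairs 6 and 7. For 3730 genes the knockout difference itself differed between the sets. Genes called in both sets were higher in both in 589 cases, lower in both in 385 and opposite in 245, where lists drawn independently would share 327, 176 and 484. The differences of the sets correlated at r = 0.30 across genes, which are not independent replicates. Array weights, which gave the arrays of pairs 6 and 7 the lowest weights, raised the count to 8320 genes.

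The largest falls included the cytokine genes Il1b, Il10, Tnf and Il1a, beside a median difference of macrophage markers of -3.25 in pairs 1 to 5 and -0.12 in pairs 6 and 7. Il1b, encoding interleukin-1β, fell by 6.99 (SE 0.65, adjusted p = 7.48e-06), with -8.16 in pairs 1 to 5 and -4.04 in pairs 6 and 7, both past the threshold. The anti-inflammatory cytokine gene Il10 fell too (-6.14, SE 0.60, adjusted p = 1.05e-05; -6.67 and -4.83 in the 2 sets, both called). Il1a fell by 5.14 (SE 0.67, adjusted p = 7.93e-05), with -5.95 and -3.11 within the sets. Ccrl2, Dusp2, Gbp8 and Clec10a also fell in all 7 pairs and passed in both sets, with pooled differences of -5.51, -5.38, -5.30 and -5.12. Other large falls rested on pairs 1 to 5. Cd83 fell by 6.39 over all pairs, with -8.04 in pairs 1 to 5 and -2.25 in pairs 6 and 7 (adjusted p = 0.0571), and the sets differed (adjusted p = 0.000151). Tnf differed by -8.48 there and by 0.28 in pairs 6 and 7 (adjusted p = 0.876), and the sets differed (adjusted p = 1.77e-05). Acod1 (-8.39 and 1.20), Igsf6 (-7.05 and -1.06) and Clec4e (-6.95 and -0.71) likewise passed in pairs 1 to 5, did not pass in pairs 6 and 7, and differed between the sets. The knockout means of Il1a (6.66), Il10 (7.25), Acod1 (6.46), Gbp8 (5.82) and Clec10a (6.19) lay under the brightness limit of 7.27, so the size and rank of these falls are limited by background.

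The largest rises included both cellular retinoic acid binding proteins. Crabp2 rose by 5.06 (SE 0.45, adjusted p = 7.2e-06), with 5.83 in pairs 1 to 5 and 3.13 in pairs 6 and 7, and Crabp1 rose by 4.90 (SE 1.01, adjusted p = 0.00179), with 5.24 and 4.04. Brinp3 (5.53), the potassium channel gene Kcnj15 (4.98) and the protease gene Mcpt8 (4.11) rose too and passed in both sets of pairs. So did Cthrc1, a secreted protein of matrix-forming cells (3.84), Fibin (3.74) and Adgrd1 (3.55). C1qtnf1 (3.69), Tnmd, encoding tenomodulin (3.63), the water channel gene Aqp5 (3.58) and the limb transcription factor gene Tbx4 (3.58) rose over all pairs. Those 4 genes passed in pairs 1 to 5 and not in pairs 6 and 7, where they differed by 1.05, -0.11, 2.02 and 0.50. Wild type means under the brightness limit of 7.27 likewise limit the size of the rises of Brinp3 (5.18), Aqp5 (6.00), Cthrc1 (6.02), Tbx4 (6.16), Mcpt8 (6.43), Tnmd (6.53), Adgrd1 (6.61), Crabp2 (7.03) and C1qtnf1.

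**Figure D2:**
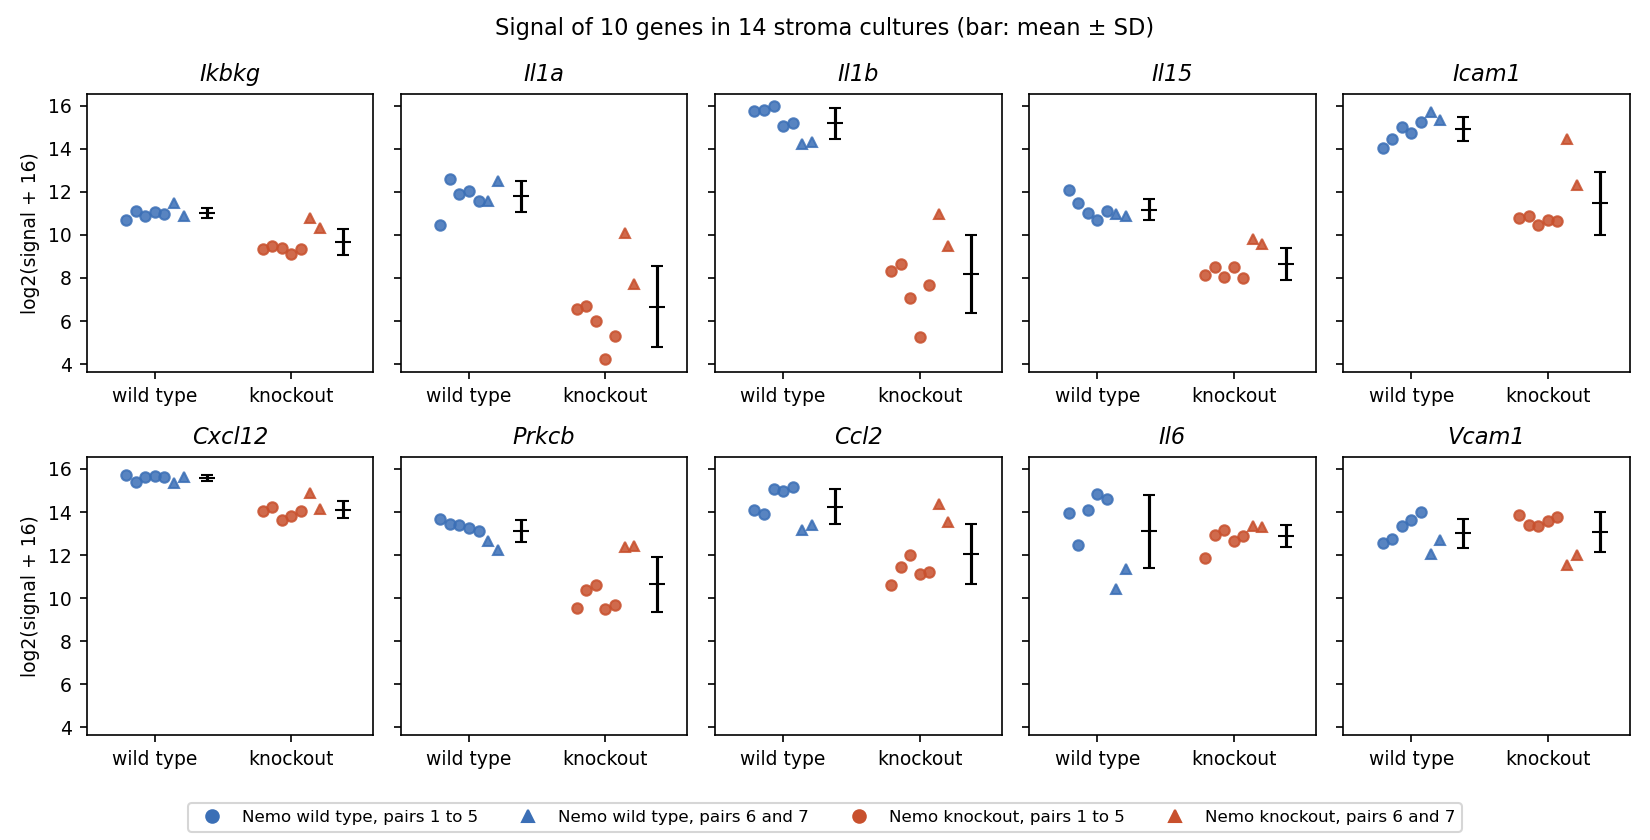
Signal of 10 genes, as log2(signal + 16) on the vertical axis, in 7 wild type and 7 knockout cultures; points are arrays, shaped by set of pairs, and bars give the mean ± SD of a group. Ikbkg, Il1a, Il1b, Il15, Icam1 and Cxcl12 were lower in the knockout in all 7 pairs, whereas Il6 and Vcam1 did not pass the test over all pairs.

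Genes described as NF-κB targets fell as a group. Of 43 tested, 30 fell, 4 rose and 9 did not pass, with a median difference of -2.21 (31 lower and 4 higher adjusted over the list alone). The smallest p-values belonged to the NF-κB subunit genes Rel (-2.79, SE 0.21, adjusted p = 1.34e-06) and Relb (-2.35), to Il1b, and to Birc3, an inhibitor of apoptosis (-2.86); each passed in both sets of pairs. Icam1, a leukocyte adhesion molecule, fell by 3.47 (SE 0.52, adjusted p = 0.00021) and passed in both sets. Its level was 14.46 and 12.30 in knockout replicates 6 and 7, and 10.44 to 10.87 in knockout replicates 1 to 5. The shared estimate of the spread may thus be too small for its test in pairs 6 and 7. Camera gave an adjusted p = 1.39e-11, and the call was lost with an estimated correlation (adjusted p = 0.313). The list's median was -2.63 in pairs 1 to 5 and -0.80 in pairs 6 and 7, where 13 members fell and 6 rose (camera adjusted p = 0.000773), and the sets differed (camera adjusted p = 9.55e-11). With an estimated correlation these gave adjusted p = 0.521 and adjusted p = 0.177, and the list's mean per array differed by -0.44 in pairs 6 and 7 (SE 0.33). From wild type to knockout that mean rose from 12.56 to 12.79 in pair 6 and fell from 12.81 to 11.70 in pair 7. In pairs 1 to 5 the fall went with a median difference of -3.25 in macrophage markers. Il6 did not pass over all pairs (-0.22, SE 0.59, adjusted p = 0.787) and went opposite ways within the sets: -1.28 in pairs 1 to 5 and 2.44 in pairs 6 and 7, both past the threshold. The chemokine gene Cxcl5 rose in both sets (2.85 and 3.13). Vcam1, an adhesion molecule, differed by 0.07 (SE 0.39, adjusted p = 0.897).

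Components of the NF-κB machinery fell too. Of 31 tested, 16 fell, 2 rose and 13 did not pass (17 and 2 adjusted over the list alone), with a median of -0.60 (camera adjusted p = 4.03e-05). With an estimated correlation the adjusted p was 0.331. Beside Rel, Relb and Birc3, Nfkbib, an inhibitor of NF-κB, fell by 1.87 (SE 0.19, adjusted p = 1.17e-05), and so did Birc2 (-0.68; -0.79 and -0.40 in the sets, the latter not called). The median was -0.76 in pairs 1 to 5 and -0.25 in pairs 6 and 7, with macrophage markers at -3.25 and -0.12.

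Chemokine genes changed in both directions. Of 22 tested, 13 fell, 3 rose and 6 did not pass (15 and 3 adjusted over the list alone; median -1.89; camera adjusted p = 0.000191, and adjusted p = 0.313 with an estimated correlation). Cxcl12, the stromal chemokine that attracts B cells and haematopoietic progenitors, fell in all 7 pairs by 1.45 (SE 0.17, adjusted p = 3.54e-05), with -1.63 and -0.99 in the 2 sets, both called. Ccl5 (-4.05) and Cxcl16 (-2.55) fell over all pairs and in pairs 1 to 5, but did not pass in pairs 6 and 7 (-1.43 and -0.66). Ccl2 fell by 2.21 (SE 0.54, adjusted p = 0.00525) on the strength of pairs 1 to 5 (-3.37); it differed by 0.69 in pairs 6 and 7 (adjusted p = 0.346), and the sets differed (adjusted p = 3.82e-05). The list's median was -2.33 in pairs 1 to 5 and -0.34 in pairs 6 and 7, where 1 member fell and 3 rose. Macrophage markers had medians of -3.25 and -0.12 in the same sets.

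Stromal factors described as supporting B cells changed in both directions. Of 30 tested, 9 fell, 6 rose and 15 did not pass, the same counts as adjusted over the list alone (median -0.10, camera adjusted p = 0.252, fry adjusted p = 0.00267). The medians were -0.33 in pairs 1 to 5, where 13 fell and 8 rose, and -0.05 in pairs 6 and 7, where 6 fell and 4 rose. Il15, a lymphocyte growth factor, fell by 2.52 (SE 0.31, adjusted p = 5.26e-05), with -3.04 and -1.22 in the 2 sets, both called, and Cxcl12 and Icam1 fell as above. Tnfsf13b, encoding the B-cell survival factor BAFF, differed by -0.72 (SE 0.30, adjusted p = 0.0673). Prkcb, encoding protein kinase C β, known from earlier work to be induced in stroma by CLL cells, fell by 2.46 (SE 0.46, adjusted p = 0.000967). That fall rested on pairs 1 to 5 (-3.43, adjusted p = 1.7e-09), against -0.04 in pairs 6 and 7 (adjusted p = 0.954), and the sets differed (adjusted p = 1.3e-05). Macrophage markers had medians of -3.25 and -0.12 there. Among 10 protein kinase C and D genes tested, 3 fell and 4 rose (3 and 4 adjusted over the list alone; median 0.29, mean -0.14, camera adjusted p = 0.969). Beside Prkcb, Prkcd (-1.62; -1.94 and -0.81, both called) and Prkch (-1.32) fell and Prkd1 rose (2.13). Prkch (-1.83 and -0.06) and Prkd1 (2.68 and 0.75) did not pass in pairs 6 and 7.

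Macrophage markers fell in the knockout arrays of pairs 1 to 5. All 27 tested were lower over all pairs (27 adjusted over the list alone), with a median of -2.34 (camera adjusted p = 1.13e-11, and adjusted p = 0.331 with an estimated correlation). Adgre1, the gene of the F4/80 antigen, fell by 3.25 (SE 0.39, adjusted p = 4.38e-05), as did the fungal receptor gene Clec7a (-4.10), Aif1 (-3.56) and the co-stimulatory gene Cd86 (-2.97). The median was -3.25 in pairs 1 to 5, where all 27 fell. It was -0.12 in pairs 6 and 7, where 2 fell and 1 rose (camera adjusted p = 0.242), and the sets differed (camera adjusted p = 1.84e-17, and adjusted p = 0.177 with an estimated correlation). The 2 that fell in pairs 6 and 7 were Adgre1 (-1.43) and Aif1 (-1.50). Outside the list, the macrophage lectin gene Clec10a differed by -4.56 in pairs 1 to 5 and by -6.53 in pairs 6 and 7. Spic, described below, also passed as lower in both sets. The list's median near 0 in pairs 6 and 7 therefore does not exclude a change in some macrophages there. The mean of the macrophage list per array was 14.21 to 14.72 in wild type cultures, where stromal markers averaged 11.39 to 11.98. It was 14.26 and 13.88 in knockout replicates 6 and 7, and 10.62 to 12.07 in knockout replicates 1 to 5. Wild type cultures thus carried strong macrophage signal beside that of stromal cells. Markers of B cells showed a similar split: 10 of 15 fell and none rose (11 adjusted over the list alone; median -1.72, camera adjusted p = 6.5e-06, and adjusted p = 0.313 with an estimated correlation), with medians of -2.61 and -0.37. The members with the smallest p were Bank1 (-2.72, with -2.71 and -2.73 in the sets), the MHC class II genes H2-Aa (-5.02, to a mean of 6.40 that lies under the brightness limit) and Cd74 (-2.67), which macrophages also express, and Ighm (-3.36). Cd74 (-3.22 and -1.27) and Ighm (-3.93 and -1.96) did not pass in pairs 6 and 7.

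**Figure D3:**
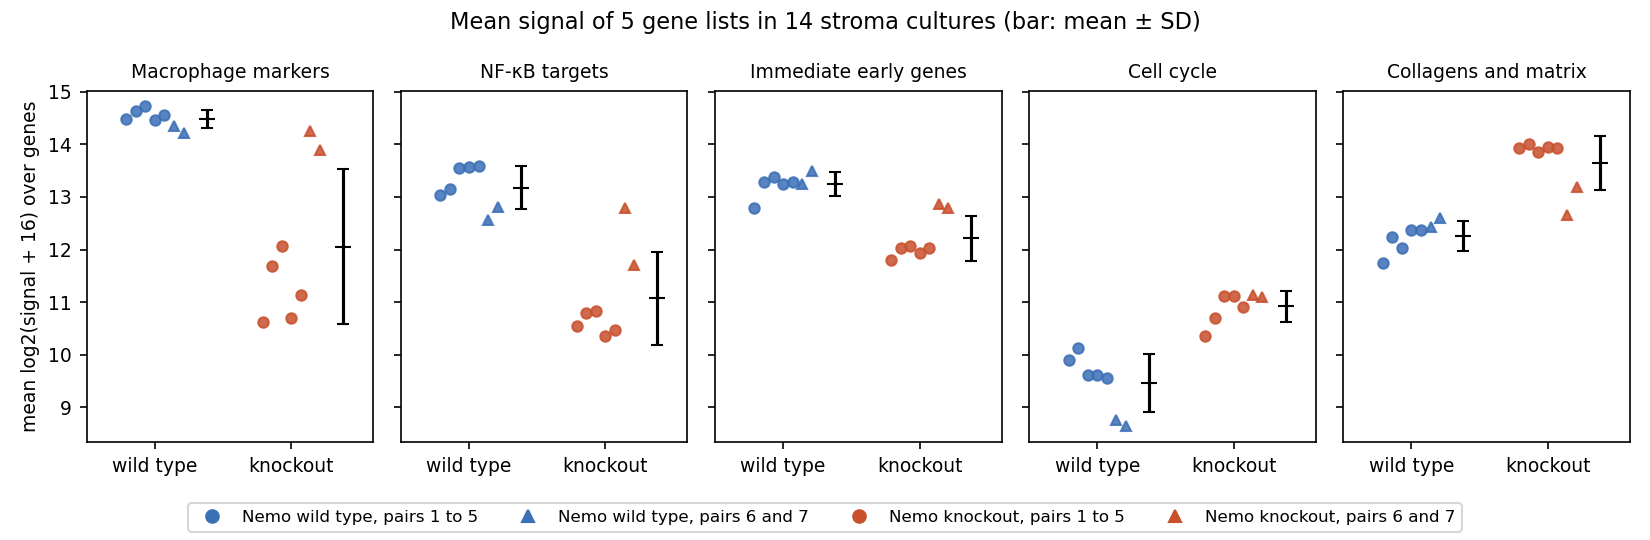
Mean log2(signal + 16) over the tested genes of 5 lists in each of 14 cultures, with points shaped by set of pairs and bars giving the mean ± SD of a group. Macrophage markers separated the knockout arrays of pairs 1 to 5 from all others, with a median difference of -3.25 there and -0.12 in pairs 6 and 7, whereas cell cycle genes were higher in both sets (1.28 and 2.29).

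Interferon-stimulated and MHC class I genes fell in pairs 1 to 5, where macrophage markers had a median of -3.25. Of 35 interferon-stimulated genes, 16 fell and 1 rose (16 and 1 adjusted over the list alone; median -0.86, camera adjusted p = 0.000191, and adjusted p = 0.313 with an estimated correlation). Rsad2, an antiviral effector, fell by 4.05 (SE 0.65, adjusted p = 0.000335), Oas2 by 2.57, Oas1a by 1.35 and the immunoproteasome gene Psmb9 by 1.33. The list's median was -1.07 in pairs 1 to 5 and -0.11 in pairs 6 and 7, where no member passed with limma, and the sets differed (camera adjusted p = 0.000973, and adjusted p = 0.219 with an estimated correlation). Of 16 genes of MHC class I presentation, 9 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.81, camera adjusted p = 0.000801, and adjusted p = 0.313 with an estimated correlation). H2-K1 fell by 1.82 in all pairs and by 1.10 in pairs 6 and 7 (adjusted p = 0.00376). H2-D1 (-1.63), H2-M3 (-1.45) and Tapbp (-0.99) fell over all pairs and did not pass in pairs 6 and 7 (-0.48, -0.43 and -0.14). The median of this list was -1.08 and -0.06 in the 2 sets.

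Immediate early genes, induced within minutes of many signals, fell. Of 18 tested, 10 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.77, camera adjusted p = 0.000191, and adjusted p = 0.313 with an estimated correlation). The medians were -0.86 in pairs 1 to 5 and -0.78 in pairs 6 and 7, where 12 and 6 members fell, and the test of the difference gave a camera adjusted p = 0.1. In the same sets macrophage markers had medians of -3.25 and -0.12. Fosb fell by 2.92 (SE 0.31, adjusted p = 1.99e-05) and passed in both sets. Zfp36, which destabilises cytokine mRNAs (-2.25), Dusp1 (-1.36) and Egr2 (-2.90) also fell. These 3 fell less in pairs 6 and 7 (adjusted p for the difference of 0.0145, 0.00251 and 0.00116), where Egr2 did not pass (-1.03).

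Cell cycle genes rose in both sets of pairs. Of 38 genes of the S and M phases, 32 rose, none fell and 6 did not pass (32 adjusted over the list alone), with a median of 1.68 (camera adjusted p = 1.13e-11, and adjusted p = 0.313 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, rose by 2.55 (SE 0.21, adjusted p = 3.62e-06), Cenpf by 1.69, the ribonucleotide reductase gene Rrm2 by 1.62 and Cdk1 by 1.55, in all 7 pairs each. The median was 1.28 in pairs 1 to 5 (27 rose and 2 fell) and 2.29 in pairs 6 and 7 (35 rose), and the sets differed (camera adjusted p = 6.2e-08, and adjusted p = 0.209 with an estimated correlation). The cyclin-dependent kinase inhibitor gene Cdkn1a fell by 0.69 (SE 0.16, adjusted p = 0.00352) and passed in both sets. It belongs to the p53 targets, of which 7 of 27 fell and 6 rose (8 and 6 adjusted over the list alone; median -0.06, camera adjusted p = 0.718). Pmaip1, a promoter of apoptosis, fell by 1.34, whereas Phlda3 (0.86; 1.11 and 0.25) and Gtse1 (0.78; 0.86 and 0.55) rose but did not pass in pairs 6 and 7. Among 19 regulators of apoptosis 8 fell and none rose (8 adjusted over the list alone; median -0.68, camera adjusted p = 0.00166, and adjusted p = 0.313 with an estimated correlation). They include both inhibitors (Birc3, Birc2) and promoters of cell death (Pmaip1 and Bcl2l11, -2.09). The medians were -1.02 and 0.07 in the 2 sets, with macrophage markers at -3.25 and -0.12.

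Matrix and contractile genes rose. Of 37 collagens and other matrix proteins, 25 rose, none fell and 12 did not pass (26 adjusted over the list alone; median 1.43, camera adjusted p = 2.48e-09, and adjusted p = 0.313 with an estimated correlation). Vcan, a large proteoglycan, rose by 3.06 (SE 0.40, adjusted p = 7.37e-05; 3.86 in pairs 1 to 5 and 1.05, not called, in pairs 6 and 7), Col5a1 by 1.90, Col5a2 by 1.55 and Sparc by 1.43. The medians were 1.65 in pairs 1 to 5 and 0.59 in pairs 6 and 7, where 9 rose and 4 fell, and the sets differed (camera adjusted p = 6.72e-06, and adjusted p = 0.209 with an estimated correlation). Macrophage markers had medians of -3.25 and -0.12 in the same sets. Of 16 contractile genes, 9 rose and none fell (9 adjusted over the list alone; median 0.68, camera adjusted p = 0.00588, and adjusted p = 0.313 with an estimated correlation). The medians were 0.73 and 0.48 in the sets (camera adjusted p = 0.0557 in pairs 6 and 7). Tagln rose 3.03-fold, Tpm1 by 1.43 (1.73 and 0.67, the latter not called), Smtn by 1.38 and Actn1 by 0.68; with the mean of its probe sets, Actn1 differed by 0.33 and did not pass. Among 21 matrix proteases and inhibitors 10 rose and 3 fell (11 and 4 adjusted over the list alone; median 0.86, camera adjusted p = 0.218, fry adjusted p = 0.0078). Mmp14 (1.67), the gelatinase gene Mmp2 (2.28) and Adamts1 (2.17) rose, and the urokinase gene Plau fell by 1.09. Mmp2 (2.98 and 0.51), Adamts1 (2.61 and 1.07) and Plau (-1.47 and -0.16) did not pass in pairs 6 and 7. Of 17 markers of mesenchymal stromal cells, 7 rose and 4 fell, also adjusted over the list alone (median 0.10, camera adjusted p = 0.553). Nt5e (CD73, 2.99), Pdgfra (2.43) and Thy1 (2.41) rose, whereas Cxcl12 fell. Pdgfra (3.24 and 0.40) and Thy1 (2.98 and 1.00) did not pass in pairs 6 and 7.

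Adipocyte markers fell: 9 of 16, with 1 higher, also adjusted over the list alone (median -1.07, camera adjusted p = 0.00401, and adjusted p = 0.407 with an estimated correlation). The call was also lost with the dimmest 60% of probe sets left out (adjusted p = 0.0742). Adipoq, the adiponectin gene, fell by 4.89 (SE 0.59, adjusted p = 4.68e-05), with -5.27 and -3.95 in the 2 sets, and Pparg, the master regulator of adipocytes, by 4.12, with -4.69 and -2.69, all past the threshold. The knockout means of Adipoq (6.18), Pparg (6.00) and Plin4 (6.88) lay under the brightness limit of 7.27, which limits the size of these falls. Plin4 (-2.49; -2.41 and -2.71) and Cebpb (-1.09; -1.38 and -0.35) fell over all pairs but did not pass in pairs 6 and 7. The list's median was -1.39 in pairs 1 to 5 and 0.05 in pairs 6 and 7, with macrophage markers at -3.25 and -0.12. Oxidative stress genes passed narrowly (6 of 18 lower and 1 higher, also adjusted over the list alone; median -0.38, camera adjusted p = 0.0482) and turned between the sets. The median was -0.86 in pairs 1 to 5, where 12 fell and 1 rose, and 0.47 in pairs 6 and 7, where 5 rose and none fell. The sets differed (camera adjusted p = 8.78e-05, and adjusted p = 0.119 with an estimated correlation), with macrophage markers at -3.25 and -0.12. The pooled call was lost with the CLL sample as a block (adjusted p = 0.0652) and with an estimated correlation (adjusted p = 0.441). It was also lost with the set of pairs as a term in the model (camera adjusted p = 0.0555) and when any 1 of 9 arrays was left out. Sod2 (-1.43), Cat (-1.65) and Gstm1 (-1.61) fell and the extracellular dismutase gene Sod3 rose (2.04). In pairs 6 and 7 Sod2 (-0.70), Cat (-0.47) and Gstm1 (-0.66) did not pass.

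The other lists did not pass camera over all pairs. Complement genes had 7 lower and 1 higher of 16 (median -0.42, adjusted p = 0.242), glycolysis and hypoxia genes 2 lower and 9 higher of 22 (0.46, adjusted p = 0.13), and growth factors 3 lower and 7 higher of 25 (0.43, adjusted p = 0.553). The median of the growth factors was 0.54 in pairs 1 to 5 and -0.59 in pairs 6 and 7, and the sets differed (camera adjusted p = 0.000137, and adjusted p = 0.172 with an estimated correlation). TGF-β responsive genes had 5 lower and 8 higher of 20 (0.50, adjusted p = 0.405), Wnt and Notch genes 6 lower and 5 higher of 22 (0.07, adjusted p = 0.76), the unfolded protein response 5 lower and 7 higher of 23 (0.11, adjusted p = 0.76), and sterol synthesis 3 lower and none higher of 20 (-0.13, adjusted p = 0.219). Osteoblast markers had 2 higher of 7 (0.29, adjusted p = 0.379), chondrocyte markers 3 lower and 2 higher of 6 (-0.34, adjusted p = 0.849), endothelial markers 2 lower and 2 higher of 6 (0.08, adjusted p = 0.915), and osteoclast markers 4 lower and 1 higher of 8 (-0.97, adjusted p = 0.135). Granulocyte markers had 1 lower and 1 higher of 4 (0.16, adjusted p = 0.712), and T and NK cell markers 2 lower of 4 (-0.85, adjusted p = 0.268). Counts adjusted over the list alone were the same for these lists, apart from 5 lower osteoclast markers. By fry the complement (adjusted p = 0.0302), TGF-β (adjusted p = 0.0078), osteoblast (adjusted p = 0.0342) and osteoclast lists (adjusted p = 0.0129) passed. In pairs 6 and 7 camera passed glycolysis and hypoxia genes (median 0.82, 8 higher, adjusted p = 0.000508), TGF-β responsive genes (0.44, adjusted p = 0.0279), matrix proteases (0.57, 5 higher, adjusted p = 0.00607) and, downward, growth factors (9 lower, adjusted p = 0.00109). With an estimated correlation none of them did (adjusted p = 0.521, adjusted p = 0.413, adjusted p = 0.343 and adjusted p = 0.343). The sets also differed by camera for the osteoblast (adjusted p = 0.0175), sterol (adjusted p = 0.00774), osteoclast (adjusted p = 0.0301), hypoxia (adjusted p = 0.0476) and Wnt and Notch lists (adjusted p = 0.048). With an estimated correlation no list differed between the sets (0 of 33, lowest adjusted p = 0.119). Median, mean and test differed in sign for the protein kinase C, chondrocyte, endothelial, unfolded protein response and Wnt and Notch lists. The p-values of limma for single genes and those of fry measure the spread between these 14 arrays. Camera compares the genes of a list with other genes, and its p-values rest also on the inter-gene correlation, preset or estimated. Permutations over genes, used below, do not measure the spread between arrays. Over all pairs 14 of 33 lists passed camera, none with an estimated correlation, and 21 passed fry.

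**Figure D4:**
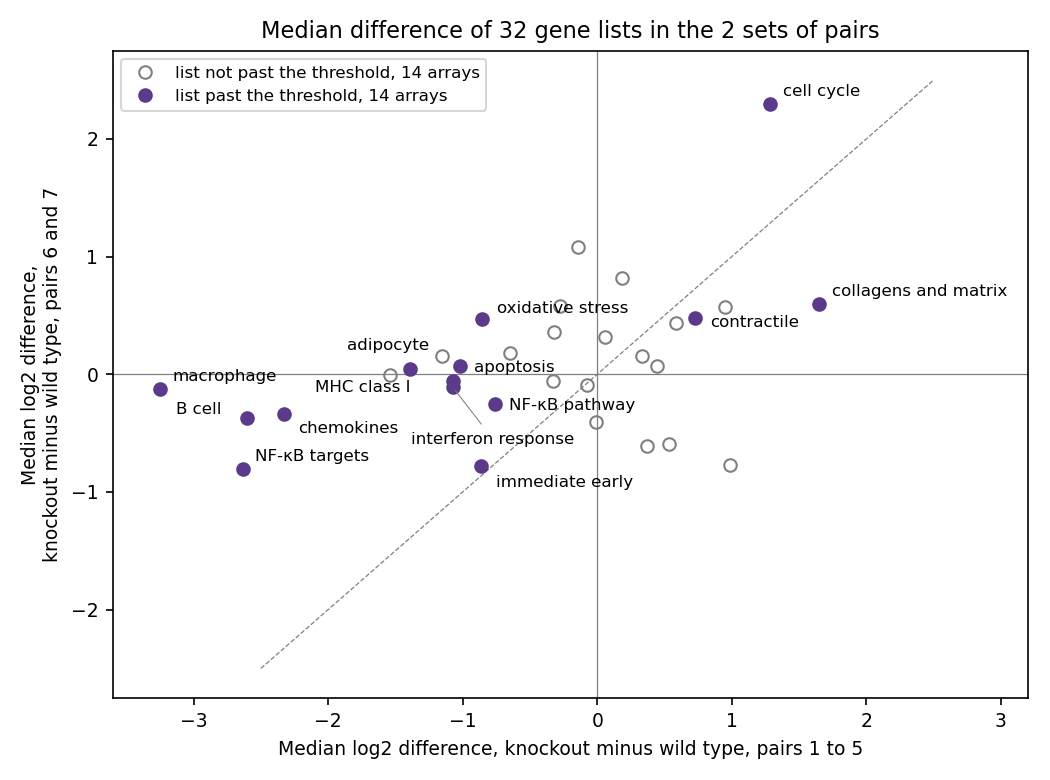
Median log2 difference, knockout minus wild type, of 32 gene lists in pairs 1 to 5 (horizontal axis) and in pairs 6 and 7 (vertical axis), with filled points for the 14 lists that passed camera over all arrays and a dashed line of equal values. Cell cycle (1.28 and 2.29) and immediate early genes (-0.86 and -0.78) lay in the same direction in both sets, whereas macrophage markers (-3.25 and -0.12) lay near 0 in pairs 6 and 7.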

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

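The groups of arrays compared here were fixed before the data were examined, but the split into sets of pairs was made after it was seen. The tests of a smaller macrophage share, of array scaling and of other splits of the arrays were written before their results; the others were chosen after the patterns were seen. A single array far from the rest of its group was looked for with Dixon's test over 256 groups of values, of which 16 (6.25%) were picked out; chance alone would pick out about 1 in 20.

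Knockout replicate 6 lay apart from the other knockout arrays for 8 of these. Mcpt8 was 8.60 there (10.36 to 11.41 in the others), Relb 10.45 (8.65 to 9.33), Birc3 13.43 (10.78 to 11.92) and Sod2 14.17 (12.34 to 13.08). Col5a2 was 14.65 (15.40 to 15.67), Col5a1 13.30 (14.18 to 14.81), Actn1 13.78 (14.06 to 14.24) and the mean of the contractile list 11.67 (12.15 to 12.43). In knockout replicate 7 the interferon-stimulated list had a mean of 10.77 (10.15 to 10.28) and the chondrocyte list a mean of 8.25 (8.96 to 9.34). Bank1 was 7.12 in knockout replicate 4 (7.47 to 7.69). In wild type replicate 1, Cd74 was 12.41 (9.58 to 10.72), the adipocyte list 11.88 (11.05 to 11.28) and the immediate early list 12.78 (13.25 to 13.49). Brinp3 was 7.79 in wild type replicate 2 (4.43 to 5.14), and Gtse1 was 9.61 in wild type replicate 7 (8.71 to 8.99).

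The knockout difference changed between pairs 1 to 5 and pairs 6 and 7 for 3730 genes. The median change of the difference, pairs 6 and 7 minus pairs 1 to 5, was 3.17 for macrophage markers, 2.06 for NF-κB targets, 1.25 for cell cycle genes and 0.57 for interferon-stimulated genes.

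All 27 macrophage markers were lower in the knockout arrays of pairs 1 to 5, against 2 in pairs 6 and 7. Poorer RNA in pairs 6 and 7 could have blunted every difference there. The difference of cell cycle genes was larger by 1.25 in those pairs (camera adjusted p = 6.2e-08, and adjusted p = 0.209 with an estimated correlation). In their mean per array it was larger by 1.34 (SE 0.30, 2-sided exact permutation p = 0.0476, the lowest that 7 pairs allow). That mean was 8.77 and 8.64 in wild type replicates 6 and 7, and 9.56 to 10.12 in wild type replicates 1 to 5. These values speak against a blunting of every difference. The sets were found in these same values, so the permutation p-value is weak support. A single list, chosen after the data were seen, does not exclude an effect of RNA quality on other genes. If a smaller macrophage share were the only change, lists of other cell types should rise by like amounts. The medians in pairs 1 to 5 of collagens, contractile genes and stromal markers were 1.66, 0.70 and 0.94, with genes shared between lists left out as planned. The median was 0.34 for all 17 stromal markers, of which 8 rose and 5 fell. The spread of the 3 medians was 0.96 (permutation p = 0.1232 over genes), so that test leaves it open. Adipocyte markers, which were not in that test, had a median of -1.39 there (11 of 16 lower and 1 higher). Those values argue against a smaller share as the only change, unless macrophages express these markers, which was not tested. A more complete loss of Nemo in pairs 1 to 5 could also account for the fall of macrophage markers. The Ikbkg difference was smaller in size by 0.98 in pairs 6 and 7 (limma adjusted p = 0.011). A more complete loss cannot be told apart from the stroma preparation, the CLL samples or RNA quality, which all differ with the set. Mouse Xist differed too (14.59 in pairs 1 to 5, 8.32 in pairs 6 and 7). These levels of the X inactivation transcript go with Nemo F/F stroma in pairs 1 to 5 and y/F stroma in pairs 6 and 7. The labels tie neither to an array. Within pairs 1 to 5, 3 of 4 sex-linked transcripts tested were lower in the knockout (median -1.80). The stroma donors may therefore differ between the groups as well, which was not tested. Time in culture may also have differed between the groups.

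NF-κB targets were lower in knockout arrays. Fewer macrophages could be the whole cause, but in pairs 6 and 7 the targets had a median of -0.80 against -0.12 for macrophage markers (one-sided permutation p = 0.0047 over genes). The list means per array differed by -0.22 there (SE 0.38), so this stays open. Array scaling is unlikely, as the median was -2.24 after quantile normalization and -2.21 before. Loss of Nemo may be the cause. In pairs 6 and 7 the list had a camera adjusted p = 0.000773, but adjusted p = 0.521 with an estimated correlation. Its mean per array differed by -0.44 there (SE 0.33), with a rise in pair 6 and a fall in pair 7. Tat-Cre exposure also went with the genotype, and time in culture may have done so, so this stays open too.

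Cell cycle genes were higher in knockout arrays. Fewer macrophages, which divide little, could raise them, but the median was 2.29 in pairs 6 and 7 (camera adjusted p = 1.05e-34; adjusted p = 0.116 with an estimated correlation; mean per array 2.42, SE 0.26), where macrophage markers had a median of -0.12. Array scaling is unlikely, with a median of 1.77 after quantile normalization and 1.68 before. DNA damage from Tat-Cre would be expected to raise p53 targets and slow division. The p53 targets had a median of -0.058. Without a wild type culture known to have had Tat-Cre, however, its effect may not be judged. Time in culture may also have differed between the groups, and its effect may not be judged either.

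Other splits of the arrays were tried for the count of changed genes. Of 100 splits of the arrays into 7 and 7, only 1, the real one with 5043 genes, had as many; the highest other split had 4122 and held all 5 knockout arrays of pairs 1 to 5 on one side. With the CLL sample as a block, only 1 of the 64 splits that part all pairs, the real one, had as many as 5762 genes. The highest other, with the labels of pair 6 exchanged, had 4083.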

How the results depend on the processing

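The alternatives were fixed before the data were examined, except the pair set term, the fits within sets of pairs and the macrophage covariate, which were added afterwards. Over 26 planned settings every named gene that passed over all pairs kept its direction, and all of the 96 named genes but Actn1, Il6 and Tnfsf13b kept their side of the threshold. Il6, from -0.96 to 0.07, and Vcam1, from -0.09 to 0.32, changed sign. NF-κB targets had medians from -2.59 to -1.87 over 26 alternatives; adjusted p was 2e-13 to 2.54e-09 over the 25 with camera and 0.000289 with fry, but the call was lost with an estimated correlation (median -2.21, adjusted p = 0.313) or with the pair set in that model (adjusted p = 0.422). The count of genes changed was 4133 to 6179 with 1 array left out. Array weights gave 8320 (4496 higher, 3824 lower), and a threshold of 0.01 gave 2842 (1544 higher, 1298 lower). The CLL sample as a fixed block gave 5762 and changed no call of a named gene or list apart from oxidative stress. The adipocyte list lost its call with the dimmest 60% left out (adjusted p = 0.0742). A list call was also lost with each of median centring, no brightness filter and no intensity trend. Actn1 lost its call with the mean of its probe sets, and Il6 gained one with array weights (-0.96, adjusted p = 0.0426). Tnfsf13b passed in 6 settings. Quantile normalization gave 4751 changed genes and median centring 4957. Lists that gained a call were hypoxia without wild type replicate 1 (adjusted p = 0.0209), without knockout replicate 4 (0.0419) and with no brightness filter (0.0173), osteoclast without knockout replicate 1 (0.0332), with a pseudocount of 64 (0.0473) and with no filter (0.0223), and matrix proteases (0.0344) and T and NK cells (0.0296) with no filter. The filter used the mean over all 14 arrays, so genes dim in 1 group stayed in, and signal over background limits the size of their differences.

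Pairs 1 to 5 alone gave 7826 changed genes (4258 higher, 3568 lower) and pairs 6 and 7 alone 1564 (953 higher, 611 lower), with fewer arrays. Among results past the threshold over all pairs or in the fit at hand, the direction in pairs 6 and 7 turned for Ccl2 (0.69), Il6 (2.44), Tnmd (-0.11), Tnf (0.28), Acod1 (1.20) and Oas1a (0.14), and for the adipocyte (0.049), apoptosis (0.070), oxidative stress (0.47) and growth factor lists (-0.59). The mean of the macrophage list as a covariate, which itself differs between the groups, left 699 genes changed (425 genes higher in knockout, 274 genes lower in knockout). Of such results it turned Ccl2 (0.21), Cat (0.057) and the adipocyte (0.14) and growth factor lists (-0.49), and left Ikbkg at -0.36 (adjusted p = 0.399). The median of the macrophage list itself (0.16) was held near 0 by the use of its mean as the covariate. NF-κB targets stayed lower (-0.68) and cell cycle genes higher (1.79). The cause was not tested.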

Other observations

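Genes with the largest differences in both sets of pairs were looked up after the data were examined. Beside those described above, Bmp2, a bone morphogenetic protein gene (-4.47 in pairs 1 to 5 and -3.97 in pairs 6 and 7), Spic, a transcription factor gene of iron-recycling macrophages (-3.88 and -4.94), and Tox2 (-3.41 and -3.69) fell in both. AA467197 (2.80 and 4.71) and Depdc1a, a mitotic gene (2.62 and 3.03), rose in both. The knockout means of Bmp2 (5.99) and Spic (6.55), and the wild type mean of Depdc1a (7.17), lay under the brightness limit of 7.27, which limits the size of their differences.

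Other genes passed in both sets with opposite signs. Kera, encoding the matrix proteoglycan keratocan (5.05 and -5.30), Igfbp3, an insulin-like growth factor binding protein (4.06 and -4.17), the opioid precursor gene Penk (3.86 and -4.91), Ecrg4 (3.52 and -3.54) and Omd, encoding osteomodulin (3.03 and -2.27), were higher in pairs 1 to 5 and lower in pairs 6 and 7. Saa3, an acute phase gene (-2.48 and 3.58), the cytokine gene Lif (-2.54 and 2.43), Il7r (-2.37 and 2.60), Cd52 (-2.61 and 2.18) and the lipid carrier gene Fabp4 (-2.34 and 2.21) went the other way.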
